A study of Mus musculus with 4 samples.

How the data were processed

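Liver RNA of 4 NSG mice was profiled by RNA sequencing. NSG is an immunodeficient strain that lacks mature B, T and natural killer cells. Untreated animals gave 2 libraries. The other 2 came from animals given JIB-04, a small-molecule inhibitor of Jumonji histone demethylases, at 55 mg/kg by oral gavage for 5 doses, 2 per week, per the labels' protocols. The control animals were untreated, not gavaged with a vehicle, per the labels' protocols. The design text describes each library as the liver of a separate mouse, so the spread within a group is a spread between animals. RNA was extracted with Trizol and libraries were made with a company's standard preparation, per the labels' protocols. Genome build GRCm39 (mm39) is named in the submitters' processing notes. The aligner, the read counter, the annotation release and the strand setting are not given in the sources used here.

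The authors deposited 1 table of FPKM values with 56748 genes, gene lengths, coordinates and biotypes, and 1 column per library. Symbols and coordinates below are those of the deposited table, counted from 1. FPKM multiplied by the deposited gene length gave whole multiples of 1 step for 100% of values in each library (tolerance 0.01), so the reads behind each value could be recovered. They came to 36793474 and 36878654 in untreated 1 and 2, and to 43283827 and 36469514 in JIB-04 1 and 2. The divisor behind the FPKM values was 0.997, 1.02, 0.990 and 1.01 times these sums, in the same order, so the authors' scaling was an effective library size. A single read in a gene of 1 kb was worth 0.0273, 0.0265, 0.0233 and 0.0272 FPKM. No interval was computed from read counts, which would cover counting error only.

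The comparison was JIB-04 against untreated liver. Values were log2(FPKM + 1), and genes with a mean FPKM of at least 1 over the 4 libraries were tested (10819 genes, 9652 of them protein-coding). The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust moderation, two-sided, 2 residual degrees of freedom before moderation), and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. A fold is the ratio of the group means of FPKM. An exact two-sided permutation test of 2 against 2 cannot give a p below 0.333, so single genes rest on the moderated test.

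Before the data were examined, 43 gene lists were fixed, 30 of pathways or functions, 10 of cell type markers and 3 of quality or sex. They held 963 symbols, of which 956 were in the table. The 40 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over those lists. Camera with an estimated correlation and fry were the alternatives. Each member was also adjusted over the list alone. The rule for the genes named was fixed at the same time: the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those called, every Cyp3a gene with Nr1i2, Nr1i3 and Por, up to 4 members of lowest p in each list, the 6 called genes with the largest difference in mean FPKM, and the sex chromosome genes. Other genes are named as chosen after their values were seen. Some results that this rule would name are not reported here.

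The test was checked on simulated libraries drawn for 10799 genes from the real means and depths, in 5 rounds with 200 genes changed in each. Genes of like level were given a common spread between replicates, averaged over them. The rates therefore do not cover genes that vary more than others at their level, and may be too favourable for the real data. Limma on log2(FPKM + 1) recovered 18.4% of genes changed 1.5-fold, 73.4% of those changed 2-fold, 96.1% of those changed 4-fold and 97.4% of those changed 8-fold. Of its 784 calls 120 (15.3%) were false, but of the 656 calls with at least 100 reads on average 12 (1.83%) were. Most false calls thus had fewer than 100 reads. In the real data 17 of the 232 called genes had fewer than 100 reads on average. Voom on simulated reads recovered 51.2%, 84.4%, 96.1% and 98.2% at the same folds, with 4.10% false calls. All list methods gave a planted list an unadjusted p under 0.05, whereas the real lists were called on adjusted p. Of 200 lists with no planted change, unadjusted p was under 0.05 in 6 with the preset correlation, in 0 with the estimated correlation and in 13 with fry. Genes were drawn independently, so correlation between the genes of a real list was not simulated.

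Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, rescaling to TPM with and without the 50 most abundant and the mitochondrially encoded genes, quantile normalization, centring on the median, limma with neither trend nor robust moderation, voom on recovered reads, protein-coding genes only, an adjusted p under 0.1, an absolute log2 change of at least 1, the replicate number as a block, and each library left out in turn. A minimum of 100 recovered reads on average was added after the data were seen. Without 1 library, the lone library of its group is assumed to vary like the other group.

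Shared sequence was measured with blastn 2.17.0 on GENCODE M21 transcripts (GRCm38, used for sequence only) as the percent of a gene's transcript in stretches of at least 100 bases at 98% identity or more in another gene. Of the 232 called genes 227 were in that reference, 207 of them with at most 50% shared. How the authors' counting treated reads that fit several genes is not given in the sources used here, so values of genes with more shared sequence are uncertain. Reads from a gene and from an antisense partner cannot be told apart either, since the strand setting is not given. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for the sequence comparison and the plots. No sample was left out.

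After the results were seen, gene families were formed from protein-coding symbols that share a stem (at least 5 tested members) and tested with camera in the same way. The stem rule was changed once after family results were seen, because it had put Psmc3ip, which is no proteasome subunit, among the Psmc genes. In the simulation, reads were drawn from negative binomial distributions.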

Results

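Liver RNA was sequenced from 2 untreated NSG mice and from 2 NSG mice given 5 oral doses of JIB-04 at 55 mg/kg. JIB-04 inhibits the Jumonji family of histone demethylases, which remove methyl groups from histone lysines. From 36469514 to 43283827 reads were recovered per library, and 20178 to 21465 genes had a value above 0. The 50 most abundant genes took 32.7% to 34.5% of reads. Pearson's r of log2(FPKM + 1) across tested genes, which are not independent replicates, was 0.985 between the untreated libraries and 0.984 between the JIB-04 libraries, against 0.967 to 0.972 between the groups. The first principal component separated the groups and held 60.9% of the variance. Xist, expressed from the inactive X chromosome of female cells, had FPKM between 36.5 and 47.7 in all 4 libraries, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty held 1 read in all (Uty in untreated 2).

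The comparison asked how repeated JIB-04 dosing altered hepatic gene expression, in a series whose title concerns CYP3A4, the main drug-oxidizing cytochrome P450 of human liver. In JIB-04 liver 165 genes rose and 67 fell. Cyp2c55, a cytochrome P450, rose from 2.32 ± 0.00116 to 377 ± 10.4 FPKM (SD, n = 2). The glutathione transferase gene Gstm3 rose from 60.8 ± 2.09 to 3326 ± 434, and Cyp3a11, a mouse counterpart of human CYP3A4, from 934 ± 43.8 to 6821 ± 288. Among genes that fell were Lpin1, a phosphatidate phosphatase of lipid synthesis, from 20.0 ± 2.85 to 5.92 ± 1.404, and Cyp2b13, a female-biased P450, from 176 ± 21.8 to 50.6 ± 10.4. Of the 232 called genes 196 were protein-coding (142 higher, 54 lower), 15 were pseudogenes and 13 were long noncoding RNAs. At least 2-fold differences numbered 125 upward and 47 downward, and at least 4-fold differences 49 and 13. All 232 had no overlap between groups, as did 46.4% of the tested genes, where chance gives 33.3%. Higher genes were 71.1% of calls, and 60.7% (142 higher, 92 lower) when values were rescaled to TPM without the 50 most abundant and mitochondrial genes. The number of calls fell to 30 without JIB-04 1 and to 23 without JIB-04 2, with the lone library assumed to vary like the other group. It was 156 without untreated 1 and 155 without untreated 2, and 20 without the filter on low values.

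**Figure D1:**
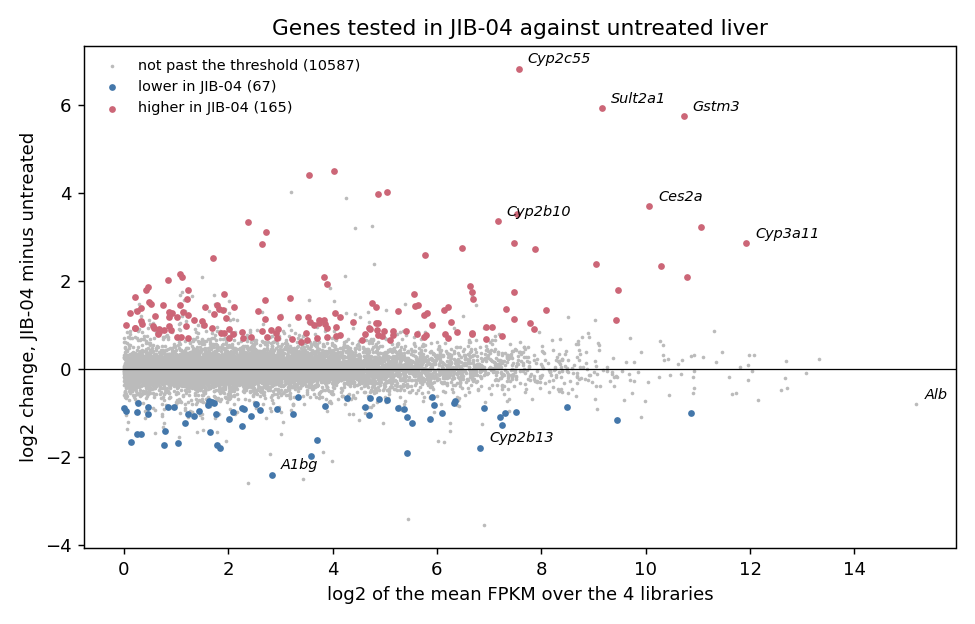
Log2 change (JIB-04 minus untreated, on the log2(FPKM + 1) scale) of the 10819 tested genes against the log2 of their mean FPKM over the 4 libraries, with 165 called higher genes in red, 67 called lower in blue and all other tested genes in grey. Cyp2c55, Sult2a1, Gstm3, Ces2a and Cyp3a11 lie far above 0 at medium to high levels, and Alb, at the right edge, was not called.

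Expression of the Cyp3a subfamily, which oxidizes many drugs and steroids, summed to 1360 ± 25.7 FPKM in untreated and 8383 ± 495 in JIB-04 liver (SD, n = 2), a 6.16-fold difference. Its 9 genes lie on chromosome 5 (GRCm39). Cyp3a11 (ENSMUSG00000056035, 145791236 to 145816774) rose 7.30-fold (log2 change 2.87, SE 0.151, limma adjusted p = 0.000284) and made up 70.0% and 67.3% of the summed FPKM in untreated 1 and 2, against 82.4% and 80.4% in JIB-04 1 and 2. It was counted with 180251 and 173752 reads in the untreated and 1444677 and 1313714 in the JIB-04 libraries. Cyp3a25 (ENSMUSG00000029630, 145914004 to 145946428) rose from 317 ± 22.4 to 1108 ± 144 FPKM (log2 change 1.80, SE 0.155, adjusted p = 0.00439). Cyp3a59 (ENSMUSG00000061292, 146016067 to 146050097), which shares 18.8% of its transcript with Cyp3a25, rose from 42.4 ± 1.71 to 315 ± 32.5 (log2 change 2.86, SE 0.133, adjusted p = 0.000188). Of the 8 tested members 3 rose, 0 fell and 5 did not pass the test, and 5 rose when adjusted over the list alone. Cyp3a16 averaged 9.09 ± 6.25 and 46.6 ± 2.93 FPKM (adjusted p = 0.185), with 13.5 in untreated 1 and 4.67 in untreated 2. Cyp3a13 averaged 16.4 ± 0.761 and 25.1 ± 1.03 (adjusted p = 0.0616, and from 0.0203 in the 4 of 17 alternatives in which it passed), Cyp3a44 21.5 and 27.3 (adjusted p = 0.530), and Cyp3a41a 16.1 and 19.9 (adjusted p = 0.423). Cyp3a41b, whose transcript is fully shared with Cyp3a41a, was at 4.33 and 2.40 in untreated and at 3.30 and 36.9 in JIB-04 1 and 2 (adjusted p = 0.710). Its log2 change of 1.58, which came from JIB-04 2, and that of Cyp3a25 were the middle values of the 8 tested members. The median of the list lies between them. Cyp3a57 was under the filter with 18, 0, 1 and 3 reads. The median log2 change of the list was 1.69 (camera adjusted p = 1.52e-08, adjusted p = 0.600 with an estimated correlation, range over alternatives 2.00e-10 to 0.600), and 1.11 without JIB-04 2. The Cyp3a25 call ended without JIB-04 1 (adjusted p = 0.0634) and without JIB-04 2 (0.0933), within a range of 1.81e-05 to 0.0933 over alternatives. Cyp3a16 passed the test without untreated 1 (adjusted p = 0.000479) and without untreated 2 (0.00636), with a highest value of 0.397 over alternatives.

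**Figure D2:**
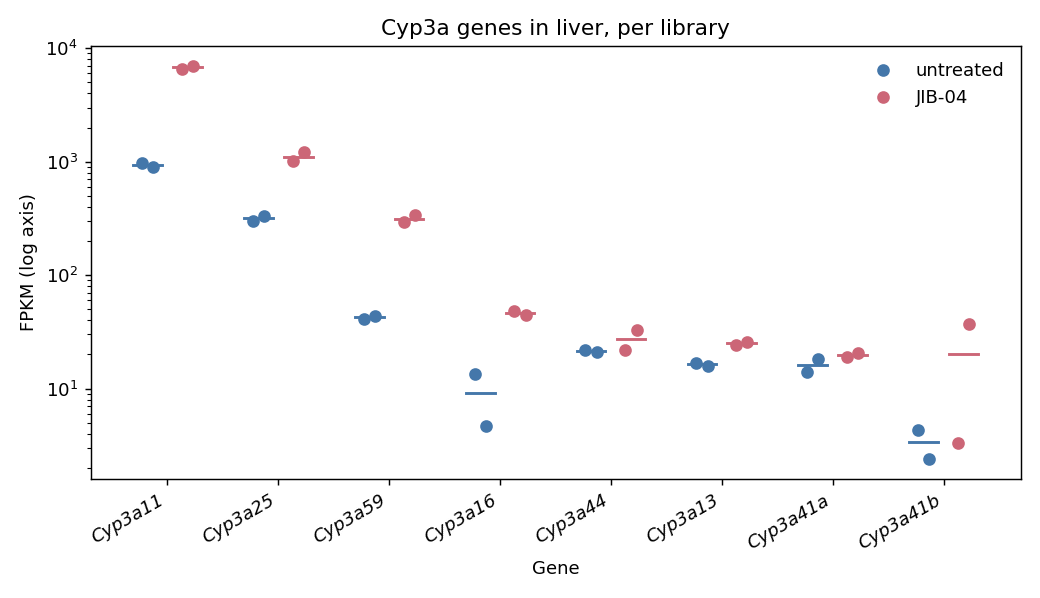
FPKM (log axis) of the 8 tested Cyp3a genes in each library, untreated in blue and JIB-04 in red, with a horizontal bar at each group mean. Cyp3a11, Cyp3a25 and Cyp3a59 are separated between groups, whereas JIB-04 1 and JIB-04 2 lie apart for Cyp3a41b, at 3.30 and 36.9.

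Targets of the xenobiotic receptors PXR and CAR, nuclear receptors that switch on drug metabolism genes in liver, had 22 of 30 tested members higher, 0 lower and 8 not past the test, or 27 and 1 adjusted over the list alone. The median log2 change of the list was 1.68 (camera adjusted p = 1.13e-33, adjusted p = 0.492 with an estimated correlation, range over alternatives 8.24e-41 to 0.492). The list took 1.39% ± 0.0405 of reads in untreated and 7.86% ± 0.227 in JIB-04 liver (SD, n = 2). Cyp2c55 (ENSMUSG00000025002, chromosome 19, 38995463 to 39031137) rose 162-fold (log2 change 6.83, SE 0.115, limma adjusted p = 2.04e-06). Gstm3 (ENSMUSG00000004038, chromosome 3, 107871012 to 107876599) rose 54.7-fold (log2 change 5.74, SE 0.149, adjusted p = 1.92e-05). Ces2a (ENSMUSG00000055730, chromosome 8, 105460635 to 105468266), a carboxylesterase that hydrolyses ester drugs, rose from 152 ± 17.1 to 1993 ± 193 FPKM (adjusted p = 0.000153). Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25597045 to 25626049), a standard CAR target, rose from 24.5 ± 2.08 to 262 ± 37.2 (adjusted p = 0.000171). The reductase Akr1b7 rose from 0.439 ± 0.109 to 32.2 ± 9.003 and Cyp2c29 from 412 ± 62.9 to 3843 ± 275. Gstm1 rose from 671 ± 141 to 2855 ± 158, and Cyp2a5, which shares 86.4% of its transcript with Cyp2a4, from 410 ± 51.2 to 2093 ± 58.2. The stress gene Gadd45b was at 2.39 ± 0.158 and 56.5 ± 30.2 (adjusted p = 0.0437), a call that ended without untreated 1 (adjusted p = 0.224) and without untreated 2 (0.220), and with voom (0.150), within a range of 0.00582 to 0.224 over alternatives. The members called higher numbered 10 without JIB-04 1 and 9 without JIB-04 2, against 17 without untreated 1 and 16 without untreated 2. Without JIB-04 1 and without JIB-04 2, in that order, the calls ended for Cyp2a5 (adjusted p = 0.0570 and 0.0689; over alternatives from 1.62e-06) and Gstm1 (0.0955 and 0.114; from 1.40e-05).

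The genes of the receptors themselves did not pass the test. Nr1i2, which encodes PXR, averaged 42.9 ± 0.952 and 46.1 ± 3.63 FPKM (SD, n = 2; adjusted p = 0.782), and Nr1i3, which encodes CAR, 10.6 ± 3.44 and 7.18 ± 1.87 (adjusted p = 0.483). Por, the reductase that passes electrons to all microsomal P450s, averaged 178 ± 41.0 and 320 ± 41.0 (adjusted p = 0.0889), and passed in 5 of 17 alternatives, among them voom (adjusted p = 0.0136) and without untreated 1 (0.0473; range over alternatives 0.0136 to 0.383). Among 29 tested regulators of P450 expression 0 were called by limma, with 3 higher and 2 lower when adjusted over the list alone. Their median log2 change was 0.06 (camera adjusted p = 0.998), and Alas1, the first enzyme of heme synthesis, averaged 136 and 203 (adjusted p = 0.0754) and passed in 2 of 17 alternatives. Of 10 tested AhR target genes Gsta1 rose and 1 fell, and the list was not called (median 0.13, camera adjusted p = 0.568). The Gsta1 call rested on 2 and 0 reads in untreated 1 and 2, against 141 and 66 in JIB-04 1 and 2. Most false calls in the simulation were of genes with few reads, so the Gsta1 call is uncertain. Cyp1a2, the AhR target in that list with the highest level, chosen after its values were seen, averaged 251 and 215 (adjusted p = 0.605).

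P450s of families 1 and 2 went both ways. Of 34 tested, Cyp2c55, Cyp2b10, Cyp2c29 and Cyp2a5 rose, while Cyp2b13, Cyp2c69 and, chosen after its values were seen, Cyp2c23 fell, from 19.0 to 10.1 FPKM (limma adjusted p = 0.0301). Adjusted over the list alone 7 rose and 9 fell. The list had a median log2 change of -0.15, a mean of 0.24 and a camera direction of down (adjusted p = 0.652). The calls of Cyp2b13, Cyp2c69 and Cyp2c23 ended without JIB-04 1 (adjusted p = 0.0563, 0.185 and 0.149) and without JIB-04 2 (0.0933, 0.241 and 0.197), and that of Cyp2c23 also without untreated 1 (0.0529) and untreated 2 (0.111). Over alternatives, adjusted p ran from 1.37e-05 to 0.135 for Cyp2b13 and from 0.00181 to 0.241 for Cyp2c69.

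Conjugating enzymes, which attach glutathione, glucuronic acid or sulfate to their substrates, had 14 of 46 higher, 1 lower and 31 not past the test, or 18 and 2 adjusted over the list alone. The list's median log2 change was 0.28 (camera adjusted p = 1.79e-08, adjusted p = 0.600 with an estimated correlation), and 0.15 with quantile normalization. The sulfotransferase gene Sult2a1 (ENSMUSG00000078798, chromosome 7, 13530171 to 13571334) rose from 18.1 ± 6.90 to 1130 ± 75.9 FPKM (SD, n = 2), 62.4-fold (log2 change 5.93, SE 0.258, limma adjusted p = 0.000717), and shares 51.5% of its transcript with Sult2a2. Gsta2, with all of its transcript in copies elsewhere, rose from 2.81 to 10.3 (adjusted p = 0.00642). The lower gene was Sult2a8, chosen after its values were seen, from 156 to 84.1 (adjusted p = 0.0460). Of the 46 conjugating enzymes, 10 are also in the PXR and CAR list, and without them 5 of 36 were higher and 1 lower, with a median of 0.13 (camera p = 0.00109, and p = 0.220 with an estimated correlation). NRF2 target genes, which answer oxidative and electrophile stress, had 7 of 31 higher and 0 lower, or 17 and 0 adjusted over the list alone (median 0.53, camera adjusted p = 2.92e-09, adjusted p = 0.548 with an estimated correlation). Those 7 were Gstm3, Gstm1, Gsta2 and Gsta1 and, chosen after their values were seen, Ephx1 (153 to 393), Gstp1 (83.3 to 163) and Ces1g (40.4 to 70.4). Of these, Gsta1 had 2 and 0 reads in untreated 1 and 2 and 141 and 66 in JIB-04 1 and 2. Its call is therefore uncertain. The glutathione transferases and the epoxide hydrolase Ephx1 are conjugation and detoxification enzymes. Nqo1, a further NRF2 target chosen after its values were seen, averaged 5.66 and 9.19 (adjusted p = 0.190) and Hmox1 20.7 and 18.5 (adjusted p = 0.707). Of 20 drug and bile transporters 3 rose and 0 fell, or 6 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.220). The uptake transporter Slco1a4 rose from 45.8 ± 6.21 to 157 ± 20.0, the basolateral exporter Abcc3 from 50.9 ± 12.7 to 155 ± 7.12, and Abcb11, the bile salt export pump, from 73.7 ± 9.23 to 129 ± 2.03 (adjusted p = 0.0398). The efflux pump gene Abcb1a averaged 1.65 and 6.01 (adjusted p = 0.0564) and passed in 5 of 16 alternatives.

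In the set just described, calls were lost without a JIB-04 library. For Sult2a1 adjusted p was 0.0563 without JIB-04 1 and 0.0689 without JIB-04 2 (lowest over alternatives 8.52e-08), for Slco1a4 0.0815 and 0.0742 (lowest 1.37e-05), for Abcc3 0.149 and 0.163 (lowest 0.00010002), for Gsta2 0.111 and 0.123, for Ephx1 0.0684 and 0.123, and for Gstp1 0.144 and 0.147. Abcb11, Sult2a8 and Ces1g were not called without any of the 4 libraries, at 0.145, 0.159 and 0.161 without untreated 1, 0.0536, 0.0698 and 0.117 without untreated 2, 0.173, 0.191 and 0.171 without JIB-04 1, and 0.226, 0.154 and 0.123 without JIB-04 2. Gstp1 was not called without untreated 1 either (0.0698). Gsta1, at 0.0285 ± 0.0403 and 2.66 ± 1.10 FPKM, was called with all 4 libraries and without untreated 1, but stood at 0.0537 without untreated 2, 0.0955 without JIB-04 1 and 0.0594 without JIB-04 2. The sulfotransferases Sult2a3 (0.133 ± 0.115 to 23.3 ± 4.02), Sult2a5 (28.7 ± 0.0932 to 344 ± 31.4) and Sult2a7 (0.512 ± 0.331 to 12.6 ± 6.13, adjusted p = 0.0463) were also among the 12 largest rises. Sult2a7 was not called without untreated 1 (adjusted p = 0.182), untreated 2 (0.134) or JIB-04 2 (0.0753), nor with voom (0.0975), a pseudocount of 0.1 (0.0580) or centring on the median (0.0529). Abcb11 was not called with quantile normalization (0.0524) or with neither trend nor robust moderation (0.0600) either.

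The protein-coding genes with the largest falls had varied functions. A1bg (ENSMUSG00000022347, chromosome 15, 60768708 to 60794861), a female-biased secreted protein gene, fell from 12.7 ± 0.407 to 1.64 ± 0.742 FPKM (SD, n = 2; log2 change -2.40, limma adjusted p = 0.00528). The steroid dehydrogenase Hsd3b2 fell from 19.7 ± 5.11 to 4.24 ± 1.28 (adjusted p = 0.0250), Cyp2c69 from 68.4 ± 24.8 to 17.1 ± 0.932, and Cyp39a1, a bile acid synthesis enzyme, from 2.97 ± 0.0561 to 0.494 ± 0.00745 (adjusted p = 0.00528). Bmf, a promoter of cell death, fell by 1.79 on the log2 scale, Etnppl, a phospholipid-breakdown enzyme, by 1.72, Dnai1, a ciliary dynein gene, by 1.68, Lpin1 by 1.61, the carbonic anhydrase Car14 by 1.28 and Ren1, the renin gene, by 1.23. A1bg was called without each library in turn. The others named here, Cyp2b13 included, lost their calls without JIB-04 1 (adjusted p between 0.0563 for Cyp2b13 and 0.185 for Cyp2c69) and without JIB-04 2 (between 0.0753 for Lpin1 and 0.241 for Cyp2c69). Ren1 was not called without untreated 2 (0.0903) or with neither trend nor robust moderation (0.0515) either. A1bg lost its call without the filter on low values (0.102).

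**Figure D3:**
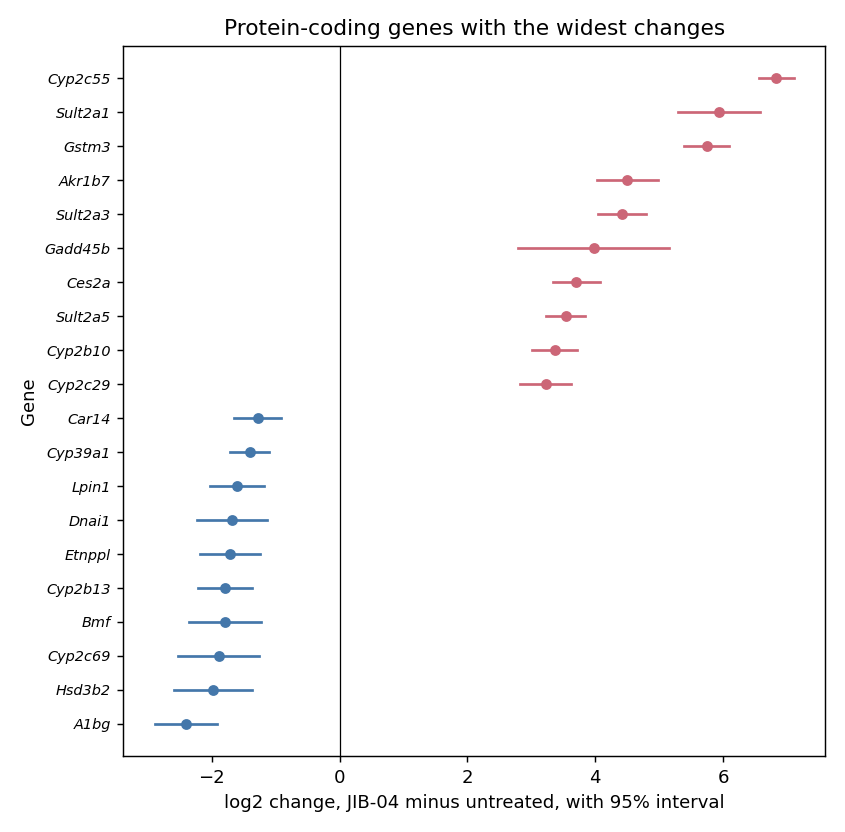
Log2 change (JIB-04 minus untreated, on the log2(FPKM + 1) scale) with its 95% limma interval for the 10 protein-coding genes with the largest rise, in red, and the 10 with the largest fall, in blue. Rises reach 6.83 for Cyp2c55, and falls reach -2.40 for A1bg.

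Lipid, bile acid and intermediary metabolism genes showed small shifts with few called genes. Among 24 genes of fatty acid synthesis 1 fell (Lpin1) and 0 rose, or 3 and 0 adjusted over the list alone (median log2 change -0.30, camera adjusted p = 0.00227, adjusted p = 0.801 with an estimated correlation). Srebf1, the transcription factor of lipogenesis, chosen after its values were seen, averaged 99.7 ± 47.3 and 29.7 ± 5.81 FPKM (adjusted p = 0.168). The list's median turned to 0.14 without untreated 2 (camera adjusted p = 0.579) and was -0.67 without untreated 1 (3.64e-16, the lowest over alternatives). Cholesterol synthesis genes were positive in 21 of 25, with 0 called by limma and 1 higher adjusted over the list alone (median 0.29, camera adjusted p = 0.00155, adjusted p = 0.801 with an estimated correlation). The list member Hmgcs1 averaged 103 and 174 (adjusted p = 0.0617) and passed in 5 of 17 alternatives. The list's call ended without untreated 1 (median 0.10, adjusted p = 0.496) and without JIB-04 1 (0.116), and its median was 0.49 without untreated 2. Of 15 bile acid synthesis genes Cyp39a1 fell and 0 rose, or 2 and 1 adjusted over the list alone (median -0.02, camera adjusted p = 0.620). Cyp7a1, the rate-limiting enzyme, averaged 43.8 ± 3.28 and 18.5 ± 6.04 (adjusted p = 0.0605) and passed in 6 of 17 alternatives. Fatty acid oxidation and PPARA targets had 0 of 32 called by limma, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.611), with a median of 0.16 without untreated 1 (adjusted p = 0.0418) and of -0.20 without untreated 2 (adjusted p = 0.000382; highest over alternatives 0.990).

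Amino acid and urea metabolism genes were negative in 24 of 31 and lower as a list, with 1 higher and 0 lower past the test over all genes, or 3 and 10 adjusted over the list alone (median log2 change -0.25, camera adjusted p = 0.000274, adjusted p = 0.685 with an estimated correlation). The higher gene was Oat, ornithine aminotransferase, from 143 ± 15.1 to 297 ± 36.6 FPKM (SD, n = 2; limma adjusted p = 0.0248). Cbs averaged 52.4 and 30.1 (adjusted p = 0.0504) and Ass1, of the urea cycle, 699 and 368 (adjusted p = 0.0612), and each passed in 8 of 17 alternatives (from 0.00684 for Cbs and 0.00770 for Ass1). Gluconeogenesis and glycolysis genes had 0 of 25 called, with 0 higher and 5 lower adjusted over the list alone (median -0.25, camera adjusted p = 0.00985, adjusted p = 0.632 with an estimated correlation), with medians of -0.10 without untreated 1, -0.06 without untreated 2 and -0.05 without JIB-04 1, where the list was not called (adjusted p = 0.116). G6pc, glucose-6-phosphatase, averaged 106 and 45.6 (adjusted p = 0.111) and passed in 1 of 17 alternatives. Genes of periportal hepatocytes, which carry out urea and glucose synthesis, were lower as a list, with 2 of 28 lower and 0 higher, or 11 and 3 adjusted over the list alone (median -0.23, camera adjusted p = 0.000274, adjusted p = 0.600 with an estimated correlation). The median was -0.36 without JIB-04 2. The 2 were Etnppl and Uox, the urate oxidase gene (202 ± 21.0 to 94.8 ± 11.3, adjusted p = 0.0205). Pericentral hepatocyte genes split, with 5 of 28 higher and 2 lower, or 7 and 8 adjusted over the list alone, a median of -0.11, a mean of 0.30 and a camera direction of down (adjusted p = 0.990). The 5 were Gstm3, Cyp2c29, Cyp2a5, Gstm1 and Oat, of which the first 4 are PXR and CAR targets in the list used here. The 2, chosen after their values were seen, were Gulo (210 to 104, adjusted p = 0.0140) and Slc13a3 (13.1 to 5.91, adjusted p = 0.0469). Calls ended without JIB-04 1 for Oat (0.125), Uox (0.119), Gulo (0.120) and Slc13a3 (0.224), without JIB-04 2 for the same genes (0.192, 0.177, 0.143 and 0.271), without untreated 2 for Oat (0.0731) and Uox (0.0611), and without untreated 1 for Slc13a3 (0.116).

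Female-biased liver genes also went both ways. Of 27 tested, Cyp2b10, Sult2a1, Sult2a7 and, chosen after its values were seen, Prom1 (0.833 to 3.57 FPKM, adjusted p = 0.0226) rose, and A1bg, Cyp2b13 and Cyp2c69 were among those that fell. Adjusted over the list alone 7 rose and 5 fell, and the median was -0.03, the mean 0.32 and the camera direction up (adjusted p = 0.990). Male-biased genes had 1 of 17 higher (Gstp1) and 0 lower, or 2 and 0 adjusted over the list alone, with a median of -0.13, a mean of 0.04 and a camera direction of down (adjusted p = 0.990). The Prom1 call ended without untreated 1 (0.0731), JIB-04 1 (0.133) and JIB-04 2 (0.0933).

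JIB-04 inhibits histone demethylases of the Jumonji family, and the list of genes of this family was not called. Of 23 tested 0 passed limma's threshold, also when adjusted over the list alone, with a median log2 change of -0.04, a mean of 0.01 and a camera direction of down (adjusted p = 0.990). Jmjd6 averaged 3.32 and 5.15 FPKM (adjusted p = 0.107) and Kdm5b 1.36 and 1.89 (adjusted p = 0.344). HIF target genes, 23 tested, had a median of -0.04, a mean of 0.07 and a camera direction of up (adjusted p = 0.976). Of these, Aldoa, a glycolytic enzyme, averaged 20.6 and 28.7 FPKM (adjusted p = 0.125) and Ldha, lactate dehydrogenase, 203 and 121 (adjusted p = 0.1295), which passed with voom (0.0213) and without untreated 2 (0.0470).

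Of the ribosomal protein list all 47 tested members had positive changes, 1 of them (Rpl12, 40.2 to 67.1 FPKM, limma adjusted p = 0.0362) past the test over all genes and over the list alone (median log2 change 0.28, camera adjusted p = 1.20e-10, adjusted p = 0.632 with an estimated correlation). Heat shock genes had 2 of 18 higher and 0 lower, or 3 and 1 adjusted over the list alone (median 0.26, camera adjusted p = 0.00138, adjusted p = 0.632 with an estimated correlation). The 2, Hspa1a (0.348 to 1.72, adjusted p = 0.0387) and Hspa1b (1.12 to 4.79, adjusted p = 0.0407), share 74.1% and 78.5% of their transcripts with each other. Integrated stress and unfolded protein response genes had 1 of 28 higher and 0 lower, or 6 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.0198, adjusted p = 0.600 with an estimated correlation). The 1 was Pdia4, a folding enzyme of the endoplasmic reticulum (55.9 to 91.4, adjusted p = 0.0398), and the list was not called without untreated 1 (adjusted p = 0.0955) or JIB-04 1 (0.0715), or at a mean FPKM of at least 5 (0.103), with medians of 0.18 without JIB-04 2 and 0.09 without the filter on low values. The calls of Rpl12, Hspa1a, Hspa1b and Pdia4 ended without each of the 4 libraries, with adjusted p of 0.133, 0.114, 0.138 and 0.159 without untreated 1, 0.118, 0.0925, 0.0840 and 0.109 without untreated 2, 0.144, 0.165, 0.133 and 0.165 without JIB-04 1, and 0.195, 0.123, 0.0768 and 0.191 without JIB-04 2. With neither trend nor robust moderation those of Rpl12 (0.0546), Hspa1b (0.0523) and Pdia4 (0.0580) also ended, and with quantile normalization those of Hspa1a (0.0525) and Pdia4 (0.0508).

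Circadian clock genes were negative in 16 of 18, with 0 called by limma over all genes and 0 higher and 6 lower adjusted over the list alone (median log2 change -0.30, camera adjusted p = 6.74e-05, adjusted p = 0.548 with an estimated correlation). The clock output gene Hlf averaged 9.34 and 5.98 FPKM (adjusted p = 0.0617) and Per1 10.04 and 6.68 (adjusted p = 0.0910), and they passed in 4 and 2 of 17 alternatives. Glucocorticoid-induced genes had 1 of 19 lower and 0 higher, or 5 and 0 adjusted over the list alone (median -0.25, camera adjusted p = 0.0149, adjusted p = 0.600 with an estimated correlation). The 1 was Zbtb16, a transcription factor (2.17 to 0.575, adjusted p = 0.0351), which was not called without untreated 1 (0.0604), untreated 2 (0.121), JIB-04 1 (0.133) or JIB-04 2 (0.200). That list was not called without untreated 1 (median -0.11, adjusted p = 0.321) or JIB-04 1 (0.0526).

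Among inflammatory, plasma protein and growth lists only complement and coagulation was called. Acute phase genes had 2 of 30 higher and 1 lower, over all genes and adjusted over the list alone (median log2 change 0.07, camera adjusted p = 0.145). Orm3 rose from 31.8 to 75.3 FPKM (limma adjusted p = 0.0199) and Crp from 93.2 to 151 (adjusted p = 0.0447), while Hamp, which encodes the iron hormone hepcidin, fell from 2473 to 1248 (adjusted p = 0.0318). This list passed without untreated 1 (median 0.54, adjusted p = 7.77e-09; highest over alternatives 0.909). Interferon-stimulated genes had 0 of 40 called by limma, also adjusted over the list alone (median 0.07, camera adjusted p = 0.151), and passed without JIB-04 1 (median 0.16, adjusted p = 0.0289) and without the filter on low values (0.0465; highest over alternatives 0.839). Complement and coagulation genes had C2 higher (9.16 to 19.7, adjusted p = 0.0137) and 0 lower of 32, over all genes and adjusted over the list alone, while 23 were negative and the list was lower (median -0.14, camera adjusted p = 0.0178, adjusted p = 0.801 with an estimated correlation). It was not called without untreated 1 (median -0.09, adjusted p = 0.492) or JIB-04 2 (0.0920), and its median was -0.22 without untreated 2 and -0.24 with quantile normalization. Of 19 p53 targets Trp53inp1 rose (13.6 to 40.4, adjusted p = 0.00528) and 0 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.485). Of 17 cell cycle genes Cdc20 (0.645 to 3.57, adjusted p = 0.0195) and Ccnb2 (0.742 to 2.91, adjusted p = 0.0223), both of mitosis, rose and 0 fell, with 3 and 0 adjusted over the list alone, a median of -0.01, a mean of 0.16 and a camera direction of up (adjusted p = 0.485). The cell cycle list passed without JIB-04 2 (median 0.26, adjusted p = 0.000568) and without the filter on low values (median 0.15, 9.53e-06; highest over alternatives 0.926). Extracellular matrix genes had 0 of 14 called by limma, also adjusted over the list alone (median 0.14, camera adjusted p = 0.611), and passed without untreated 1 (median 0.23, adjusted p = 0.0482; highest over alternatives 0.981). Calls ended without JIB-04 1 for Orm3 (0.118), Crp (0.171), Hamp (0.193), C2 (0.0955), Trp53inp1 (0.0947), Cdc20 (0.134) and Ccnb2 (0.162), and without JIB-04 2 for the same genes (0.177, 0.220, 0.205, 0.123, 0.0933, 0.0933 and 0.191). They also ended without untreated 1 for Crp (0.114), Cdc20 (0.0536) and Ccnb2 (0.0655), and without untreated 2 for Orm3 (0.0539), Crp (0.163), Hamp (0.0696) and C2 (0.0536). Crp was not called with quantile normalization (0.0679), centring on the median (0.0541) or neither trend nor robust moderation (0.0604) either.

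Hepatocyte markers had 0 of 20 called by limma, also adjusted over the list alone, with 17 negative (median log2 change -0.13, camera adjusted p = 0.00699, adjusted p = 0.632 with an estimated correlation), and took 18.9% ± 0.310 of reads in untreated and 12.96% ± 1.27 in JIB-04 liver (SD, n = 2). Alb, the albumin gene, took 10.9% and 11.2% of reads in untreated 1 and 2, and 7.35% and 5.40% in JIB-04 1 and 2 (adjusted p = 0.144). The hepatocyte list was not called without untreated 1 (adjusted p = 0.0752) or JIB-04 1 (0.0508), and its median was -0.22 without JIB-04 2 and -0.23 with quantile normalization. Kupffer cell markers, of resident macrophages, were negative in 13 of 14 with 0 called by limma, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0343, adjusted p = 0.819 with an estimated correlation), and the list was not called without untreated 1 (median -0.03, adjusted p = 0.490) or JIB-04 1 (-0.02, 0.779), or with a pseudocount of 0.1 (0.0506), with medians of -0.26 without untreated 2 and -0.29 without JIB-04 2. Stellate cell and fibroblast markers had 0 of 13 called and 1 lower adjusted over the list alone, with 11 negative (median -0.24, camera adjusted p = 0.0187, adjusted p = 0.801 with an estimated correlation), and were not called without untreated 1 (median -0.07, adjusted p = 0.490) or JIB-04 2 (-0.12, 0.0760), with a median of -0.37 on TPM without the 50 most abundant and mitochondrial genes. Erythroid markers had 0 of 8 called and 1 lower adjusted over the list alone, with 7 negative (median -0.92, camera adjusted p = 0.00360, adjusted p = 0.632 with an estimated correlation). Hba-a1, a globin gene, averaged 1274 ± 456 and 655 ± 422 FPKM (adjusted p = 0.548), and the list's median was -0.38 without JIB-04 1, -1.44 without JIB-04 2 and -0.16 without the filter on low values.

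Endothelial markers had 0 of 17 called, also adjusted over the list alone (median log2 change -0.09, camera adjusted p = 0.0788), and passed without untreated 2 (median -0.23, adjusted p = 0.00221) and without the filter on low values (0.0472), while the median turned to 0.02 without untreated 1 (0.915, the highest over alternatives). Recruited monocyte and macrophage markers had 0 of 7 called and 1 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.153), and passed without untreated 2 (adjusted p = 0.0322) and JIB-04 2 (0.0154; highest over alternatives 0.875). Neutrophil markers had 0 of 3 called and 1 higher adjusted over the list alone, with a median of -0.15, a mean of 0.97 and a camera direction of up (adjusted p = 0.485). S100a8 averaged 4.54 ± 3.02 and 49.6 ± 18.9 FPKM (SD, n = 2; limma adjusted p = 0.131) and passed in 2 of 17 alternatives, and the list passed without untreated 1 (median 0.84, adjusted p = 0.000609; highest over alternatives 0.838). Cholangiocyte markers had 0 of 3 called and 1 higher adjusted over the list alone (median 0.11, camera adjusted p = 0.611). Lists with fewer than 3 tested members had no list test. Of the lymphocyte markers, Ighm averaged 8.71 ± 7.02 and 18.0 ± 9.04 (adjusted p = 0.635) and passed in 1 of 16 alternatives. Of the markers of pancreas, gut and fat, Fabp2, a fatty acid binding protein gene, fell from 80.3 ± 8.81 to 36.2 ± 5.26 (adjusted p = 0.0195), and Cela1 averaged 9.48 and 3.71 (adjusted p = 0.137) and passed in 2 of 17 alternatives. Of the sex chromosome genes, Xist was tested (adjusted p = 0.781). Fabp2 was not called without untreated 1 (0.0640), JIB-04 1 (0.142) or JIB-04 2 (0.111). Mitochondrially encoded mRNAs were positive in 13 of 13, with 0 called by limma, also adjusted over the list alone (median 0.19, camera adjusted p = 0.0420, adjusted p = 0.801 with an estimated correlation). Their median was 0.32 without untreated 2. They were not called without untreated 1 (median 0.09, adjusted p = 0.429) or JIB-04 2 (0.11, 0.216), or with quantile normalization (median 0.04, adjusted p = 0.387), rescaling to TPM (0.0623), the same without the 50 most abundant and mitochondrial genes (0.0642), voom (0.0842), a mean FPKM of at least 5 (0.0805) or pseudocounts of 0.1 (0.0699) and 0.5 (0.0554), so that the call was lost in 11 of 19 alternatives, fry and the estimated correlation included.

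Of the 40 lists tested, camera with the preset correlation called 20, 9 higher and 11 lower in JIB-04, and 10 of them kept their call without each library in turn. Those 10 were the Cyp3a, PXR and CAR, conjugating enzyme, NRF2, heat shock and ribosomal protein lists upward, and the amino acid, circadian, periportal and erythroid lists downward. With an estimated correlation camera called 0 (smallest adjusted p 0.492), and for each of the 20 lists that adjusted p was the highest of its alternatives. Fry, which tests whether a list moves 1 way on balance and does not set it against other genes, called 1, the PXR and CAR list (adjusted p = 0.0256), and its mixed test for change in either direction called 29.

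**Figure D4:**
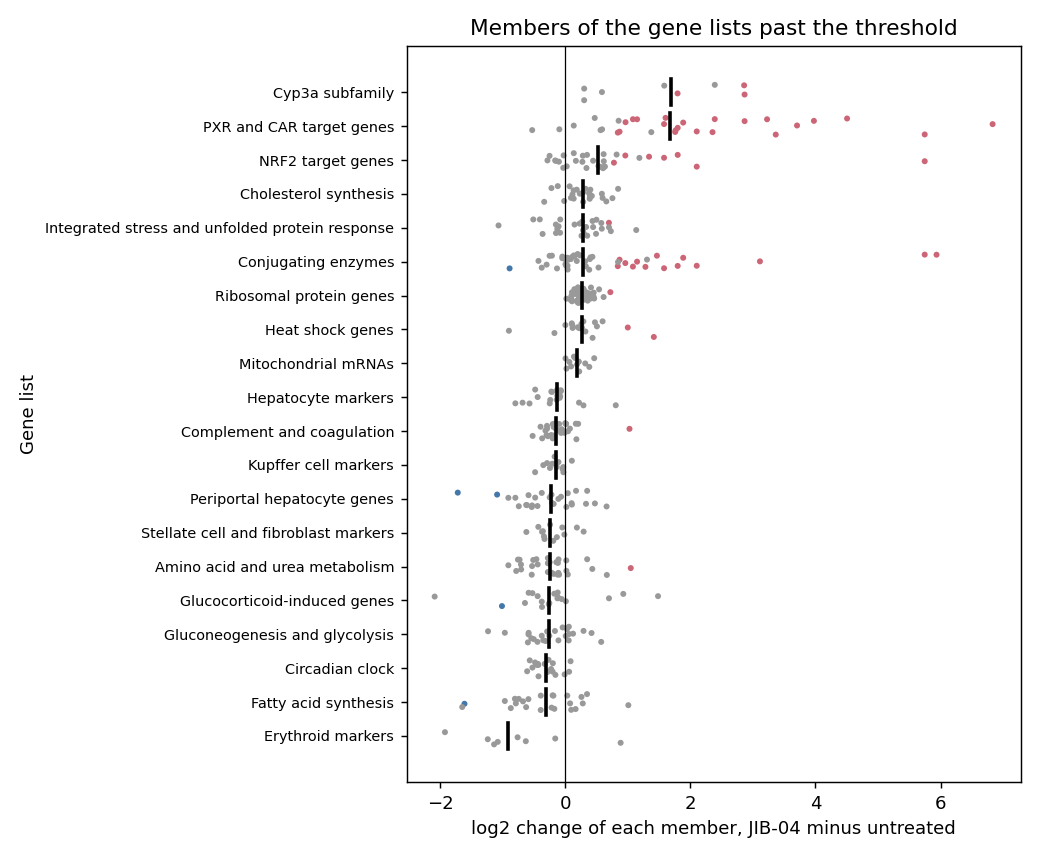
Log2 change (JIB-04 minus untreated, on the log2(FPKM + 1) scale) of each tested member of the 20 gene lists called by camera, with members called higher in red, called lower in blue and others in grey, and a black bar at each list's median. The Cyp3a and the PXR and CAR lists have medians of 1.69 and 1.68, and the erythroid list has the lowest, -0.92.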

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

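The minimum of 100 reads was chosen after the data were seen. With 2 libraries per group, counts of calls moved widely while directions of the named called genes held. Of 160 named genes 5 changed sign in some alternative, 0 of them called by limma. Without the filter on low values, which more than doubled the genes tested, 20 genes were called, 20 higher and 0 lower by limma (2205 at an unadjusted p under 0.05, and 516 called by voom on the filtered genes). Voom on recovered reads called 516 (309 higher, 207 lower) and included 220 of the 232 genes. Testing only protein-coding genes gave 397 (256, 141), and only genes with at least 100 reads on average 393 (254, 139). An adjusted p under 0.1 gave 464 (294, 170) and a log2 change of at least 1 in size 131 (100, 31). Leaving out 1 library gave 23 to 156 calls, 22 to 107 higher and 1 to 54 lower. Without JIB-04 1, 30 genes were called, and without JIB-04 2, 23, and each kept 22 of the 232. Rescaling to TPM without the 50 most abundant and mitochondrial genes gave 234 (142, 92). The remaining scalings, filters, pseudocounts and the fit with neither trend nor robust moderation gave 156 to 232 calls, and no scaling moved the median of all genes by over 0.1.

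List calls numbered 20. They fell to 0 with an estimated correlation and to 1 with fry, under which the Cyp3a median of 1.69 had adjusted p of 0.600 and 0.0522. With only 2 residual degrees of freedom the correlation is poorly known. In simulation 0 of 200 unchanged lists had an unadjusted p under 0.05 with camera at an estimated correlation, but genes were drawn independently there. Among the 20 called lists the estimated correlation ran from -0.03 (circadian clock) to 0.80 (Kupffer cell markers). The simulation therefore cannot tell which correlation setting suits these lists. The fatty acid synthesis list turned to 0.14 without untreated 2 (adjusted p = 0.579) and was -0.67 without untreated 1, and the fatty acid oxidation list to 0.16 without untreated 1 (0.0418) and was -0.20 without untreated 2. The causes of these changes were not tested, apart from the smaller number of genes or samples that each setting makes. Over all alternatives, list results were unchanged in 661 cases, gained a call in 12, lost it in 63 and turned in 2, and named genes in 2387, 135, 160 and 0. Of 50 named genes called changed, 10 were never lost: Akr1b7, Ces2a, Cyp2b10, Cyp2c29, Cyp2c55, Cyp3a11, Cyp3a59, Gstm3, Sult2a3 and Sult2a5 (highest adjusted p 0.0457, for Cyp3a11). A further 19 were lost only without a JIB-04 library or without the filter.

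The libraries share only a replicate number. With that number as a replicate block 357 genes were called (236 higher, 121 lower), 227 of the 232 among them, and deviations of same-numbered libraries had a correlation of -0.0492.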

Other observations

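Chosen after the results were seen were the tests of gene families, of clock phase, of read composition, of other cell types and of sample splits. For shared sequence, scaling and list overlap, predictions were written before those tests were run, but on patterns already seen in the results.

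Of the called genes, 120 higher and 52 lower were in none of the fixed lists. Families were therefore formed from protein-coding genes sharing a symbol stem, with at least 5 tested members, and the stem rule was narrowed once after results were seen, to keep unrelated genes with longer endings out. Of 303 families 16 passed camera at the preset correlation (15 higher, 1 lower) and 0 with an estimated correlation (adjusted p = 0.997), so these are hypotheses. All 16 medians kept their sign under the 4 scalings and without each library. In the Sult2a family, sulfotransferases in a cluster on chromosome 7, 6 of 7 tested genes rose and Sult2a8 fell (median log2 change 3.11, 3.04 to 3.56 under the scalings and 2.67 to 3.59 without 1 library, adjusted p = 4.08e-09). Sult2a6 had 14.9 and 14.4 FPKM in untreated 1 and 2, against 86.8 and 102 in JIB-04 1 and 2, and Sult2a2, nearly all of whose sequence is shared with Sult2a1 and Sult2a5, had 56.0 and 65.8 against 391 and 434. Carboxylesterases (Ces) had 5 of 12 higher (median 0.55, 0.32 to 0.54 under the scalings and 0.47 to 0.60 without 1 library, adjusted p = 0.000171), among them Ces1d, the main triglyceride hydrolase of the group, from 433 ± 15.4 to 947 ± 162 FPKM (SD, n = 2; limma adjusted p = 0.0267). The Cyp2c family, with Cyp2c55 and Cyp2c29 higher, was the family that passed downward, with 11 of 13 members negative (median -0.53, -0.64 to -0.53 under the scalings and -0.68 to -0.36 without 1 library, adjusted p = 0.0153).

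Proteasome subunit genes were positive in 35 of 37 (Psma, Psmb, Psmc and Psmd; median log2 change 0.38), with 0 called by limma, and took 0.2495% of reads in untreated and 0.328% in JIB-04 liver. The 4 subunit families each passed camera, with medians between 0.31 and 0.40 under the scalings, and between 0.25 and 0.50 without 1 library (adjusted p = 0.000744, 0.0328, 0.00594 and 8.49e-05 in that order). Cct chaperonin genes, which fold newly made proteins, were positive in 7 of 7 (median 0.21, 0.15 to 0.21 under the scalings and 0.14 to 0.36 without 1 library, adjusted p = 0.0410). Phospholipases (Pla2g) had 2 of 5 higher, Pla2g6 (10.6 to 25.0 FPKM) and Pla2g12a (4.01 to 14.3), with a median of 0.46 (0.38 to 0.46 under the scalings and 0.44 to 0.56 without 1 library, adjusted p = 0.0227).

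For the rise of PXR and CAR targets, shared reads and scaling were weighed. Of the 22 members called higher 17 had at most 50% of their transcript in near-identical stretches of another gene, which argues against reads passed between copies as the whole cause. Under the 4 scaling alternatives at least 20 members of the list were called higher. What the tables leave open is the cause among treated animals: JIB-04 itself, the gavage or its vehicle, and the handling differed together between the groups. Activation of these receptors by the compound may account for the rise, as a hypothesis untested here.

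For the fall of hepatocyte and periportal genes, reads taken up by induced transcripts were weighed first. Genes called higher took 1.89% and 1.99% of reads in untreated 1 and 2, against 9.31% and 9.77% in JIB-04 1 and 2, which would lower every other gene by a predicted log2 shift of -0.12. The median of all tested genes was 0.0068, and -0.00615 when values were scaled to plain read totals, so no such general shift was seen. More cells of other types would raise their markers, of which 12 of 64 in 7 other lists were positive, 18.8%, and 9.38% to 39.1% without 1 library. Markers move together within a mouse, and their mean log2 value overlapped between the groups, at 3.87 and 3.58 in untreated 1 and 2 and 3.46 and 3.65 in JIB-04 1 and 2. So more cells of other types and a lower expression within hepatocytes cannot be told apart with 2 mice per group.

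For the lower circadian clock list, the time of collection was weighed, since the labels give none. A shift in time would move genes that peak with Arntl against those of the opposite phase. The median log2 change of the first was -0.43 over 3 tested genes (Nfil3 -0.43, Cry1 -0.43, Clock 0.09) and of the second -0.35 over 10, with 9 of them negative. Both medians were negative, but with 3 genes of which 1 was positive, a time difference and an effect of treatment cannot be told apart.

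Members shared with the PXR and CAR list were tested as the source of the NRF2 list's rise: without the 5 shared genes, 26 remained with a median of 0.35 and 3 called (camera p = 5.47e-06, and p = 0.0510 with an estimated correlation). Only genes named in both lists were removed, so targets of PXR and CAR outside the list used here may remain among the 26. The test therefore cannot separate a rise through NRF2 from a rise through those receptors. Without the shared genes, the medians of 3 further lists were negative: -0.12 for 15 transporters (camera p = 0.312), -0.17 for 23 pericentral genes (0.0165) and -0.17 for 29 P450s of families 1 and 2 (0.00517), with p = 0.396, 0.156 and 0.0871 with an estimated correlation. The 7 Cyp3a genes other than Cyp3a11 had a median of 1.58, with 2 called higher (camera p = 2.47e-07, and 0.0949 with an estimated correlation). That median is the value of Cyp3a41b, whose rise came from JIB-04 2 and whose transcript is fully shared with Cyp3a41a. Of 13 pseudogenes called higher, 1 had over 50% of its transcript shared with a gene called higher, 4 had any and 9 none. The 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05, and the real split called 232 genes against at most 0 in the others, by limma.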
